A study of Mus musculus with 2 samples.

How the data were processed

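RNA was sequenced from 2 cultures of mouse bone marrow cells, 1 for each retroviral vector, and the deposited table gives 1 column of whole-number read counts per culture. Per the labels' protocols, lineage-negative marrow cells of C57BL/6 mice were enriched on magnetic columns, transduced, sorted for green fluorescence 3 days later and grown at 10000 cells in methylcellulose (MethoCult M3434) for about 3 weeks, after which RNA was extracted on RNeasy columns. Each library was assigned to its group by the vector named in its labels, and each column of the table by its name. No column of the table was left unmapped (0).

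The values are counts, which the authors deposited as reads per Ensembl gene without normalization. Per the submitters' processing notes, HISAT2 2.2.1, SAMtools, featureCounts, Subread and edgeR were used with the GRCm38 genome build. The notes as used here give neither their order nor their settings. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. A set of 7 pseudogenes on chromosome 1 that are copies of mitochondrial sequence held 1.55% of the counts of the EVI1-WT library and 1.50% of those of the EVI1+18 library. Reads from near-identical copies can therefore stand at more than one gene. For some of the genes named below the share of common sequence is given, and most other genes were not compared. Without a known strand setting, reads from overlapping genes on opposite strands cannot be told apart.

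The table lists 55487 gene IDs, of which 55141 matched GENCODE release M21 on GRCm38, the build named in the notes. Symbols, gene types and coordinates were taken from that release. The unmatched IDs held 0.0487% and 0.0429% of the counts and stayed in the library totals. Totals were 20480447 counts for EVI1-WT and 20981903 for EVI1+18. A count of 0 allows up to 3 counts, which is 0.150 scaled CPM in the first library and 0.140 in the second. For 3 list symbols carried by more than 1 ID, the ID with the most reads was used.

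With 1 library per group there are no degrees of freedom for edgeR's quasi-likelihood test or any other test that rests on replicates, and none was run. Libraries were scaled with edgeR 4.0.16 (TMM, in R 4.3.3), and each gene's ratio of EVI1+18 over EVI1-WT was given a 95% exact (Clopper-Pearson) counting interval in scipy 1.17.1. These intervals and floors cover counting error only, and reads without molecular identifiers are not independent molecules. They compare the libraries, not the vectors. A gene was called 2-fold apart when its whole interval lay above 2 or below 1/2, among the 13183 genes with at least 1 scaled CPM in a library, which are the genes counted as tested. Log2 ratios were computed with a prior count of 2, which draws the ratios of low genes towards 0. Folds in the text are ratios of scaled CPM without a prior count, and a fold against a count of 0 is computed against 3 counts in that library. Such a fold leaves out the counting error of the other library. The bound of the exact interval, which ranks the genes, is lower (for Kalrn, 65.1 beside 80.6).

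Before the data were examined, 32 gene lists were fixed, together with the design, the alternatives and the rule for naming genes. For each list with at least 4 tested members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from the tested genes in 20 bins of mean expression. A list was called above or below random lists past percentiles 97.5 and 2.5. List medians were the same with genes of 0 counts set at their bound. The percentile describes these libraries and is not a test of the vectors. Genes of one list tend to be regulated together, so random lists of unrelated genes understate the spread of a list median. Of the 31 lists placed, about 1.55 would lie outside by chance if their genes were unrelated.

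The genes named are Mecom, then the 12 genes of at least 10 scaled CPM with the largest conservative fold in each direction, leaving out predicted symbols (Gm followed by digits, or ending in Rik). The conservative fold is the bound of the counting interval nearest to 1. For each list above or below random lists, up to 4 members in its direction and 1 in the other follow, by the same measure, and for each other list 2 members. Some of the genes that the rule takes are not given in the text. A few other list members were named after the values were seen.

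The calling rule was tested on simulated counts for 12711 genes with the libraries' own means and sizes, of which 200 were changed. It called 84.0% of the genes changed 3-fold and 99.0% of those changed 5-fold in the right direction, and 0 unchanged genes. The simulated counts held counting error only, with no variation between cultures. Calls of unchanged genes were therefore unlikely by construction, and the 0 says nothing about false calls between real cultures. Of 200 random lists of 20 genes, 5.5% fell outside the central range. These lists were drawn from the same genes as the lists they were placed among, so a share near this was fixed in advance. It says nothing about lists of genes that are regulated together. Alternatives covered 4 other scalings, including DESeq2 1.42.0 size factors, a loess curve on abundance, other filters, folds, intervals and prior counts, thinning of the deeper library, and other forms of the random lists. A further 5 alternatives were added after the data were seen. Leaving out a replicate was not possible.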

Results

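Gene expression was measured by RNA sequencing in mouse haematopoietic cells that carried either of 2 forms of EVI1, a zinc finger transcription factor encoded by the Mecom locus and overexpressed in a class of aggressive leukaemias. One culture was transduced with a retroviral vector (pMYs-IG) for HA-tagged wild-type EVI1 (EVI1-WT), and the other with the same vector for EVI1+18, a product of aberrant EVI1 splicing. The cells were lineage-negative bone marrow cells, which are enriched for stem and progenitor cells, and were harvested after about 3 weeks in a semi-solid medium that allows myeloid, erythroid and mixed colonies to form. The comparison asks how transcription in colonies that express the aberrant form differs from that in colonies that express the wild-type form. Each form was represented by 1 library, so no difference below has a replicate check, and the intervals given cover counting error alone. The EVI1-WT library held 20480447 counts over 21013 genes and the EVI1+18 library 20981903 counts over 21037 genes.

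Mecom (ENSMUSG00000027684; GRCm38 chromosome 3, 29951296 to 30548008, minus strand) had 3612 counts in EVI1-WT, or 180 scaled CPM, and 4481 counts in EVI1+18, or 209 scaled CPM. The level in EVI1+18 was 1.16-fold that in EVI1-WT, with a 95% counting interval of 1.11 to 1.21. Counts per gene do not separate the vector's transcript from the endogenous one or show which splice form was present, and a library without an EVI1 vector was not analysed here. The labels do not say whether the vector carried the human or the mouse sequence, and reads of a human sequence would be counted at the mouse gene only in part, so this ratio is not a measure of how strongly the 2 forms were expressed.

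Colonies expressing EVI1+18 had higher levels of red-cell and platelet genes than colonies expressing EVI1-WT, with median log2 ratios of 3.05 and 3.26 over the fixed lists. Genes of the joint mast cell and basophil list, of eosinophils and of mature neutrophils were lower, with medians of -1.59, -1.93 and -1.48. Of 13183 genes that passed the expression filter, 666 were at least 2-fold higher and 672 at least 2-fold lower in EVI1+18 beyond counting error, and 11845 were neither. The genes with the largest conservative folds in the upward direction included the red-cell water channel Aqp1 (chromosome 6, 55336432 to 55348555), at 0.250 scaled CPM in EVI1-WT and 75.3 in EVI1+18. Its ratio was 301-fold, with an interval of 129 to 930. The retinaldehyde dehydrogenase gene Aldh1a1 (chromosome 19, 20492715 to 20643465) had 22 counts in EVI1-WT and 3500 in EVI1+18, a 148-fold ratio (97.9 to 237). Its neighbour Aldh1a7, with 3 and 448 counts, was 139-fold higher (47.4 to 678), and 7.49% of its 50-base words occur in Aldh1a1. The platelet chemokine Pf4 was 70.2-fold higher (57.6 to 86.5). The soluble epoxide hydrolase Ephx2 was 139-fold higher (73.1 to 305) and the cystathionine gamma-lyase Cth 144-fold higher (61.4 to 445). Sh3bgrl2 was 164-fold higher (75 to 447), and the inflammasome sensor Nlrp6 was 118-fold higher (45.8 to 435). Kalrn and the germ-cell gene Rnf17 had 0 counts in EVI1-WT. Against 3 counts they were 80.6-fold and 91.8-fold higher, and their lower interval bounds were 65.1 and 74.2. Mid1, a ubiquitin ligase gene of the X chromosome, was 82.8-fold higher (66.8 to 104). Its pseudogene Mid1-ps1, annotated on chromosome Y, was 128-fold higher (84.6 to 205). Of the 50-base words in the Mid1-ps1 transcripts, 86.2% also occur in Mid1, whereas 15.0% of those of Mid1 occur in Mid1-ps1, so the counts of the pseudogene are the more uncertain.

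In the downward direction, the Y-linked translation factor gene Eif2s3y (chromosome Y, 1010543 to 1028847) had 2002 counts in EVI1-WT and 1 in EVI1+18, a 2145-fold ratio with an interval of 385 to 84760. The X-linked genes Xlr4c and Xlr4b had 0 counts in EVI1+18, and were at least 231-fold and at least 74.3-fold lower. They share sequence, with 46.6% of the 50-base words of Xlr4b found in Xlr4c. The water channel Aqp8 was 348-fold lower (149 to 1074). The secreted Wnt antagonist Frzb had 0 counts in EVI1+18 and was at least 145-fold lower. Hepatocyte growth factor, Hgf, was 35.0-fold lower (31.6 to 38.8), at 634 scaled CPM in EVI1-WT and 18.1 in EVI1+18. Calca, which encodes calcitonin and its related peptide, was 43.3-fold lower (28.4 to 69.4). The choline dehydrogenase Chdh and the nuclease Dnase2b were 35.7-fold (24.4 to 54.5) and 38.5-fold lower. E-cadherin, Cdh1, was 20.05-fold lower (18.02 to 22.4).

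**Figure D1:**
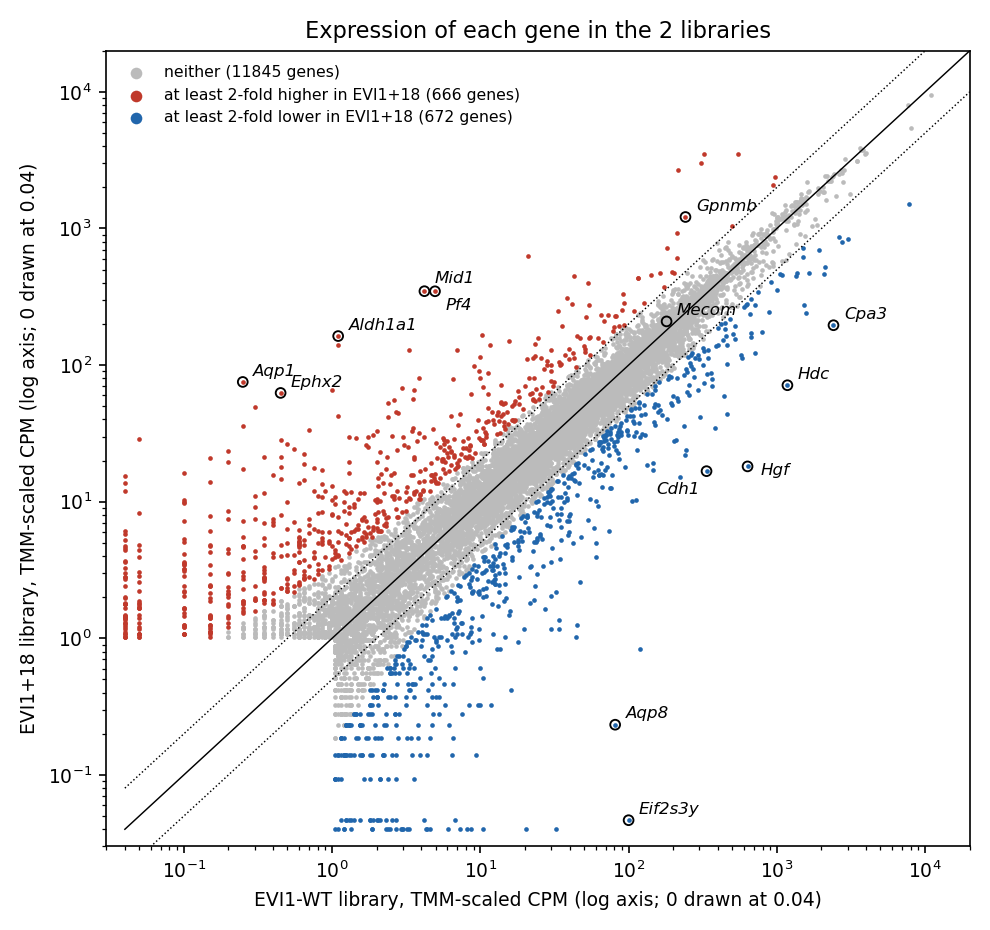
TMM-scaled CPM of each of the 13183 tested genes in the EVI1-WT library (x axis) and the EVI1+18 library (y axis), both on log axes, with 1 point per gene, a solid line at equal expression and dotted lines 2-fold away. The 666 genes in red and the 672 in blue had counting intervals wholly more than 2-fold higher or lower in EVI1+18, and Mecom lies near the solid line at 180 and 209 scaled CPM.

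Genes of the red-cell and platelet lineages were higher in EVI1+18. Of 26 erythroid genes, 23 were at least 2-fold higher and 0 lower, with a median log2 ratio of 3.05 (counting interval 2.99 to 3.19), at percentile 100 of random lists, whose central range ran from -0.21 to 0.23. Besides Aqp1, the carbonic anhydrase Car1 was 60.9-fold higher (29.3 to 152) and Trim10 47.7-fold (28.3 to 87.8). The adult globin genes, singled out after their values were seen, took 0.137% of the counts in EVI1-WT and 1.29% in EVI1+18. Hba-a1 and Hba-a2 share 72.3% of 50-base words, so their sum is more certain than either. Of 15 megakaryocyte and platelet genes, 10 were at least 2-fold higher and 1 lower, with a median log2 ratio of 3.26 against a random range of -0.28 to 0.28. They included Pf4, described above. The platelet tubulin Tubb1 had 0 counts in EVI1-WT and was 21.8-fold higher against 3 counts, with a lower interval bound of 17.2. P-selectin, Selp, was 37.1-fold higher (14.2 to 138). The exception was thrombospondin, Thbs1, which is also made by other myeloid cells and was 3.60-fold lower (3.54 to 3.66).

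Genes of the joint mast cell and basophil list, of eosinophils and of neutrophils were lower in EVI1+18. Of 21 mast cell and basophil genes, 12 were at least 2-fold lower and 3 at least 2-fold higher, with a median log2 ratio of -1.59 against a random range of -0.21 to 0.20. The mast cell carboxypeptidase Cpa3 had 2409 scaled CPM in EVI1-WT and 196 in EVI1+18, a 12.3-fold lower level (11.9 to 12.7). Histidine decarboxylase, Hdc, was 16.5-fold lower (15.7 to 17.4), the IgE receptor chain Fcer1a 11.1-fold lower (10.3 to 12) and the adenosine receptor Adora3 24.9-fold lower (17.2 to 37.5). The mucosal protease gene Mcpt1 went the other way, with 1 count in EVI1-WT and 84 in EVI1+18, a 78.4-fold ratio with an interval of 13.7 to 3133. All but 1 of 7 eosinophil genes were at least 2-fold lower, with a median log2 ratio of -1.93 against a random range of -0.53 to 0.48. Eosinophil peroxidase, Epx, was 7.49-fold lower (7.06 to 7.95), and the granule proteins Prg2 and Prg3 were 4.63-fold and 4.28-fold lower. Siglecf, also found on some macrophages, was 4.23-fold higher (3.45 to 5.23).

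Among 19 genes of secondary granules and mature neutrophils, 10 were at least 2-fold lower and 1 higher, with a median log2 ratio of -1.48 against a random range of -0.23 to 0.23. Ly6g, the surface marker of mature mouse neutrophils, was 16.8-fold lower (12 to 24.4). The chitinase-like Chil3 was 5.48-fold lower (5.33 to 5.64) and the chemokine receptor Cxcr2 6.06-fold lower (5.32 to 6.93). The ficolin Fcnb was 3.44-fold higher (2.39 to 5.06). The 14 primary granule and promyelocyte genes were less far apart, with 3 at least 2-fold lower, 0 higher and a median log2 ratio of -0.49 against a random range of -0.23 to 0.19. Among them, the granulocyte transcription factor Cebpe was 4.03-fold lower (3.57 to 4.56) and cathepsin G, Ctsg, 2.23-fold lower (2.16 to 2.30), while proteinase 3, Prtn3, stood 1.58-fold higher (1.5 to 1.66).

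Macrophage and antigen-presentation genes were higher in part. Of 21 monocyte and macrophage genes, 8 were at least 2-fold higher and 2 lower, with a median log2 ratio of 0.93 against a random range of -0.24 to 0.21. The Fc receptor Fcgr1 was 9.24-fold higher (5.89 to 15.3), the phagocytic receptor Mertk 10.5-fold (5.11 to 25.1) and the glycoprotein Gpnmb 5.02-fold (4.87 to 5.18). In EVI1-WT, Fcgr1 had 21 counts and Mertk 8. Ly6c2, a marker of inflammatory monocytes, was 4.58-fold lower (4.37 to 4.80), and 13.9% of its 50-base words occur in Ly6c1. The other gene of this list at least 2-fold lower was the macrophage marker Adgre1, at 2.60-fold (2.47 to 2.74). Of 14 genes of dendritic cells and MHC class II, 4 were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.96. The transcription factor Irf8 was 5.20-fold higher (3.70 to 7.48) and the class II gene H2-Aa 3.36-fold (2.73 to 4.17). Clec9a had 1 count in EVI1-WT and 37 in EVI1+18, a 34.5-fold ratio with an interval of 5.83 to 1400. Bst2 was 1.45-fold lower (1.36 to 1.53).

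Genes of stem and early progenitor cells split in direction. Of 19 tested, 7 were at least 2-fold higher and 3 lower, with a median log2 ratio of 0.65 against a random range of -0.24 to 0.23. The stem cell surface marker Slamf1 was 53.1-fold higher (28.7 to 111), and it is also carried by other blood cells. The transcription factors Lmo2 and Mllt3 were 3.38-fold (3.14 to 3.63) and 3.46-fold higher (2.98 to 4.02). Ikzf2 was 2.93-fold lower (2.72 to 3.16). Only 3 of 13 genes of the HOXA and MEIS1 list were expressed above the filter, too few to place among random lists. Of these, Meis1 had 6 counts in EVI1-WT and 197 in EVI1+18, a 30.6-fold ratio (13.8 to 84.5), and Igf1r was 1.11-fold lower (1.07 to 1.14).

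The 15 tested genes that have been linked to EVI1 in the literature, and the 24 tested myeloid transcription factors, lay within the range of random lists. Their median log2 ratios were -0.11 and -0.11. In the first list 2 genes were at least 2-fold higher, the erythroid and megakaryocytic regulator Gata1 at 2.54-fold (2.38 to 2.71) and Smad3, with 2 and 75 counts, at 35.0-fold (9.36 to 294). Gata2, in both lists and named after the values were seen, was 2.04-fold lower (1.99 to 2.10), just short of the rule. In the second, 5 were higher and 3 lower, among them Maf, 6.29-fold higher (3.87 to 10.8), and Id2, 4.45-fold lower (4.13 to 4.80).

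Lists of inflammatory and signalling genes had negative medians, with most members less than 2-fold apart, in the same library in which the mast cell and basophil median was -1.59. Of 23 genes of NF-kappaB signalling and inflammatory cytokines, 7 were at least 2-fold lower and 0 higher, with a median log2 ratio of -0.38 against a random range of -0.20 to 0.20. The chemokines Ccl4 and Ccl3 were 10.8-fold (9.43 to 12.5) and 7.28-fold lower (6.79 to 7.82), the inflammasome gene Nlrp3 5.48-fold lower (4.61 to 6.56) and interleukin 6, Il6, 4.48-fold lower (4.23 to 4.75). Tnfaip2 was 1.81-fold higher (1.73 to 1.90). Of 15 genes of the TGF-beta and SMAD response, 4 were at least 2-fold lower and 1 higher, with a median log2 ratio of -0.41. Besides Id2, the receptor Tgfbr1 was 2.38-fold lower (2.2 to 2.57), while Bambi, a pseudoreceptor that blocks TGF-beta signalling, was 3.71-fold higher (2.61 to 5.39). Among 21 cytokine and growth factor receptors, 5 were at least 2-fold higher and 5 lower, and the median and mean log2 ratio differed in sign, at -0.36 and 0.25. The median lay below random lists, but the list lay inside them by its mean (percentile 87.1) and without a filter (3.35). The interleukin 33 receptor Il1rl1, found on mast cells, was 10.8-fold lower (9.86 to 11.9). The common beta chains Csf2rb2 and Csf2rb were 4.48-fold (4.38 to 4.58) and 3.43-fold lower (3.37 to 3.49), and 18.4% of the 50-base words of Csf2rb2 occur in Csf2rb.

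Metabolic lists lay closer to 0 than the erythroid list (3.05) and the mast cell and basophil list (-1.59) in the same libraries. In the list of amino acid and endoplasmic reticulum stress genes, 3 of 18 were at least 2-fold higher and 1 lower, with a median log2 ratio of 0.30 against a random range of -0.20 to 0.16. Trib3, a target of the stress factor ATF4, was 4.99-fold higher (4.52 to 5.52), asparagine synthetase, Asns, 2.82-fold (2.67 to 2.97) and the mitochondrial serine hydroxymethyltransferase Shmt2 2.43-fold (2.34 to 2.52). The chaperone cofactor Sdf2l1 was 2.12-fold lower (2.0004 to 2.26). The 18 cholesterol synthesis genes had a median log2 ratio of -0.40 against a random range of -0.22 to 0.17, with 2 at least 2-fold lower and 1 higher. Cyp51 was 2.24-fold lower (2.14 to 2.35) and Fdps 2.78-fold lower (2.19 to 3.54), whereas the isomerase Idi1 was 2.33-fold higher (2.24 to 2.41). Of 22 lysosome and phagocytosis genes, measured beside a macrophage median of 0.93, 5 were at least 2-fold higher and 1 lower. Their median log2 ratio was -0.23, below random lists, and their mean was 0.067, of the opposite sign, inside random lists (percentile 81.4), as was the median against unmatched lists (2.54). The inhibitory Fc receptor Fcgr2b was 2.52-fold lower (2.41 to 2.64), the adaptor Tyrobp 1.89-fold lower (1.83 to 1.95) and the protease Ctsl 3.79-fold higher (3.46 to 4.17).

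Proliferation genes were slightly higher as sets, with no member at least 2-fold apart, in the library with the erythroid median of 3.05. The 24 genes of G2 and M phase had a median log2 ratio of 0.29 (counting interval 0.26 to 0.32), and 23 of them lay above 0. Cyclin A2, Ccna2, was 1.48-fold higher (1.41 to 1.56) and Ccnb2 1.44-fold (1.35 to 1.53), while Kif20a was 1.02-fold lower with an interval that included equality (0.935 to 1.10). The 24 genes of S phase and DNA replication had a median of 0.27, with Rfc4 1.60-fold (1.41 to 1.81) and Chaf1b 1.48-fold higher (1.33 to 1.65). The 20 splicing factor genes had a median of 0.20 against a random range of -0.19 to 0.15, but lay inside random lists by its mean (percentile 96.5) and against unmatched random lists (94.9). Srsf2 was 1.38-fold higher (1.33 to 1.43), Srsf3 1.20-fold higher (1.17 to 1.24) and Prpf8 1.07-fold lower (1.04 to 1.10).

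Other lists lay within the range of random lists. The median log2 ratio was 0.15 for 23 type I interferon response genes, -0.08 for 18 p53 targets, 0.06 for 17 heat shock and immediate early genes, -0.18 for 21 glycolysis and hypoxia genes, 0.12 for 30 cytoplasmic ribosomal protein genes, 0.13 for 20 ribosome biogenesis and MYC genes, 0.08 for 22 nuclear genes of oxidative phosphorylation and -0.17 for 13 mitochondrially encoded genes. The immediate early list lay above random lists by its mean (0.36) and with a filter at 5 CPM (0.35), and the glycolysis list below them by its mean (-0.41) and with that filter (-0.30). Single members still differed. The antiviral gene Mx1 was 8.32-fold higher (6.56 to 10.7) and Ifi27l2a 5.21-fold lower (4.16 to 6.58). The immediate early genes Fosb and Atf3 were 3.58-fold (3.15 to 4.09) and 3.55-fold higher (3.05 to 4.14). Plk2 was 5.12-fold higher (3.72 to 7.21) and Perp 2.84-fold lower (2.72 to 2.96). The lactate transporter Slc16a3 was 3.95-fold lower (3.70 to 4.22) and the oxidase Ero1l 3.00-fold lower (2.93 to 3.07). In the ribosomal, nucleolar and respiratory lists no member was 2-fold apart, and their named members ranged from mt-Nd4l, 1.33-fold lower (1.28 to 1.38), through Rps7, 1.21-fold higher (1.18 to 1.23), and Ndufb9, 1.36-fold higher (1.23 to 1.52), to Odc1, 1.70-fold higher (1.63 to 1.77).

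Markers of cells outside the myeloid colonies were scarce. Only 6 of 24 lymphoid genes and 4 of 20 stromal and endothelial genes passed the filter, with median log2 ratios of -0.86 and -1.17. The lymphoid list lay just below random lists, at percentile 2.07, with 1 gene at least 2-fold higher and 1 lower. It lay inside them without a filter (percentile 10.4), by its mean (14.9) and against protein-coding random lists (3.42), so this call rests on the setting. The interleukin 2 receptor chain Il2rb, found also on other cells, was 13.3-fold lower (6.2 to 34.1), and the transcription factor Tcf7 2.18-fold lower (1.67 to 2.86). Blnk had 1 and 23 counts, a 21.5-fold ratio with an interval of 3.49 to 884. Pdgfrb was 4.51-fold lower (2.71 to 7.88) and Thy1 2.66-fold lower (2.54 to 2.79). Of 4 sex-linked genes tested, Eif2s3y alone was 2-fold apart, and Uty was 1.26-fold lower (1.11 to 1.42). Across 31 lists, 9 lay above and 10 below random lists, the lymphoid, splicing factor, lysosome and cytokine receptor lists among them with the exceptions given.

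**Figure D2:**
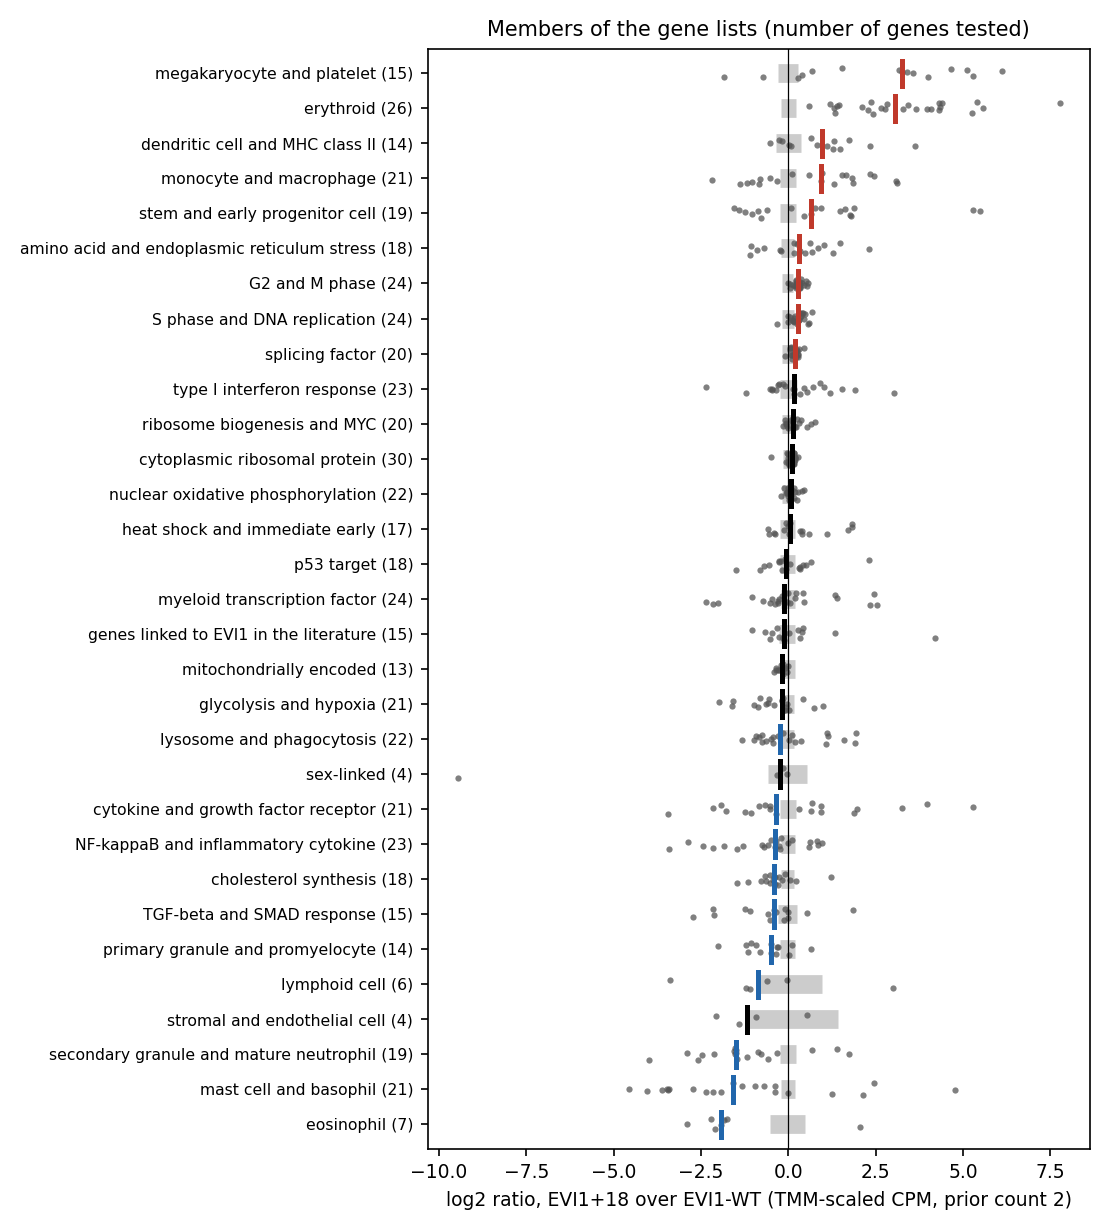
Log2 ratio of EVI1+18 over EVI1-WT (x axis) for each tested member of 31 gene lists (rows, with the number of genes tested), where dots are genes, thick ticks are list medians and grey bars are the central 95% of medians of 10000 random lists. Red ticks lie above and blue ticks below the random lists, and the megakaryocyte (3.26) and erythroid (3.05) medians lie farthest from 0 on one side and the eosinophil median (-1.93) on the other.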

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

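Counts of genes 2-fold apart, 666 higher and 672 lower as reported, ranged from 654 to 714 higher and 613 to 688 lower under the 4 other scalings, the loess curve and thinning. Without a filter they were 752 and 763, and with a wider interval 502 and 507. A filter at 5 CPM, which tests fewer genes, gave 431 higher and 468 lower. A fold of 1.5 gave 1093 higher and 1290 lower, a fold of 4 gave 294 and 218, and asking only that the ratio pass 2 and the interval exclude 1 gave 1033 and 1101. If replicate cultures varied with a coefficient of variation of 0.2, a value assumed after the data were seen and not measured, 442 and 383 genes would pass the rule, and at 0.4 there would be 284 and 192. The log2 ratio of Mecom was 0.21 as reported and 0.28 under scaling by total count, outside its counting interval but in the same direction. Scaling moved the median of all tested genes by at most 0.064. The number of lists outside random lists stayed within 8 to 11 above and 8 to 10 below under the alternatives tried. The mean over members had the opposite sign to the median for the lysosome list (0.067) and the cytokine receptor list (0.25), so neither list has a single direction; the cause was not tested. The lymphoid list lay inside random lists without a filter, by its mean and against protein-coding genes, and at 5 CPM it had too few genes to be placed. Glycolysis by its mean (-0.41) and at 5 CPM (-0.30), and immediate early genes by their mean (0.36) and at 5 CPM (0.35), moved outside. So did the stromal list against unmatched random lists, ribosomal proteins at 5 CPM and sex-linked genes by their mean, while splicing factors by their mean or against unmatched lists, lysosome genes against unmatched lists and cytokine receptors without a filter moved inside. Of 959 values of named genes under alternatives, 35 moved beyond their counting interval and 0 reversed. Depth limits low genes: with 0 counts in a library, only a bound of 3 counts can be set. With 1 library per vector no replicate could be left out.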

Other observations

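All tests and gene groups in this part were chosen after the data were seen. The embryonic globin genes were higher in the EVI1+18 library together with the adult ones: Hbb-y had 420 counts in EVI1-WT and 13533 in EVI1+18, a 30.1-fold ratio (95% counting interval 27.3 to 33.2), and Hba-x was 37.0-fold higher (16.8 to 102). Hbb-y shares 0 of its 50-base words with Hbb-bs, so its counts do not come from adult globin reads of that gene. Bcl11a, a known repressor of embryonic globin genes, was also higher, with 2 and 219 counts (102-fold, 28.0 to 849). Genes of secreted factors that were lower in EVI1+18, picked for that, included Lif at 14.6-fold (13 to 16.4), Osm at 5.24-fold (4.95 to 5.54), Il13 at 7.84-fold (6.12 to 10.2) and Csf1 at 4.19-fold (4.03 to 4.35). The platelet chemokines Pf4 and Ppbp, of the megakaryocyte list, were 70.2-fold and 16.1-fold higher, and Il1b (1.20-fold lower, 0.957 to 1.5) and Cxcl2 (1.19-fold lower, 1.02 to 1.39) were not 2-fold apart, nor by the rule were Tnf (1.41-fold lower, 1.2 to 1.67) and Vegfa (2.01-fold higher, 1.85 to 2.19).

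Of 10 amino acid response genes of the report's stress list, 3 were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.77. Ddit4, of the same list, was placed in neither this group nor the next. Of 13 genes of endoplasmic reticulum folding, some from that list and some added, 3 were at least 2-fold lower and 0 higher, with a median of -0.89. Of the lower ones, Sdf2l1 came from that list, and Pdia4 and Ero1l were added after the data were seen. Herpud1 and Dnajb9 in this group were 1.12-fold higher (1.05 to 1.2 and 1.004 to 1.24), Pdia4 was 3.61-fold lower (3.50 to 3.73) and the abundant chaperone Hspa5 was 1.86-fold lower (1.82 to 1.89). Among lysosomal and lipid-handling genes of macrophages, the higher ones included Lpl at 3.76-fold (3.60 to 3.94), Trem2 at 3.83-fold (3.32 to 4.43) and Ctsk at 7.24-fold (5.22 to 10.3), while Spp1 was 1.54-fold lower (1.52 to 1.57). Among neighbouring genes on chromosome 9, Paqr9, Trpc1 and Pls1 were 63.3-fold, 50.4-fold and 15.3-fold higher. On chromosome 1, the interferon-inducible genes Ifi203, Ifi204, Ifi207 and Ifi211 were 8.36-fold, 4.16-fold, 3.22-fold and 5.52-fold higher, while Aim2 was 1.35-fold lower (1.26 to 1.46).

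The opposite shift of lineages had erythroid and megakaryocyte genes higher. Genes of the mast cell and basophil, eosinophil and mature neutrophil lists were lower. This shift was set against scaling or a few abundant genes. Under the 4 other scalings and the loess curve the 5 medians kept their signs and none came closer to 0 than 1.42 log2 units. For the scalings this outcome was fixed in advance, because each moves all ratios alike, here by at most 0.064. For the same reason, no scaling factor can account for the distance between lists that were higher and lists that were lower. The loess curve could move genes unequally, and its medians lie within the same bound. A lower share of mast cells or basophils alone would raise the markers of every other type alike. The erythroid median instead exceeded the mature neutrophil median by 4.77 log2 units (bootstrap interval over genes 3.68 to 5.81), so those lists did not move alike. This difference restates the pattern, which was defined by the opposite directions of these lists, and is not a separate test. The bootstrap treats genes of a list as independent and covers no variation between cultures. What stays open is a difference between these 2 colony pools unrelated to the vector, because there is 1 library per vector. Colonies grown from a limited number of cells may differ in lineage by chance. The pools also differed in single genes outside the lineage lists, with Eif2s3y at 2002 and 1 counts and Xlr4c at 647 and 0. The source of those differences, treated below, is not known. An effect of the EVI1 form on lineage output is the biological explanation the design names. With these libraries it cannot be told apart from a difference between the pools.

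Eif2s3y was nearly absent from the EVI1+18 library while other genes of the Y chromosome were not. Fewer male cells would lower them all, but the median log2 ratio of Kdm5d, Uty and Ddx3y was -0.16, and Xist had 8 and 4 counts. Reads assigned to the X-linked paralogue Eif2s3x would have raised that gene by about as many reads as were lost, but it gained 191 (upper bound 390) against a loss of 2001. Gm29650, the counted gene between Eif2s3y and Uty, had 46 counts in EVI1-WT and 0 in EVI1+18, a log2 ratio of -4.63. A clone with a lost or silenced interval between Kdm5d and Uty is a candidate explanation, and the X-linked Xlr4a, Xlr4b and Xlr4c, all at 0 counts in EVI1+18, may be a second case, though 70.6% of the 50-base words of Xlr4a and 46.6% of those of Xlr4b occur in Xlr4c, so their counts may be reads of fewer genes, and gene counts cannot tell a deletion from silencing or from a difference between the mice used.

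Mid1 and its copies annotated on chromosome Y, Mid1-ps1 and Gm21742, were all far higher in EVI1+18, with Gm21742 at 1 and 616 counts. At least 73.3% of the 50-base words of each copy occur in Mid1 transcripts, so reads of near-identical copies shared between loci may account for these 3 genes being higher together. Sharing with Mid1 transcripts does not cover Gm21860 (0 and 330 counts), Gm21748 (0 and 112) and Gm47283 (4242 and 19805, 4.36-fold). These genes share 0 of their words with Mid1 and are annotated on chromosome Y near or inside these copies. With Mid1-ps1 and Gm21742 they lie between positions 90753057 and 90844040, in a single stretch. Whether that whole stretch is shared between chromosomes X and Y was not examined, so its counts need not be reads of chromosome Y. Gm15726 (3 and 170 counts) and Gm15247 (6 and 160), antisense genes within the Mid1 span on the X chromosome, were higher too, and with the strand setting unknown their reads cannot be told from those of Mid1. More copies of the whole Y chromosome do not account for the pattern, since the highest log2 ratio among Kdm5d, Uty and Ddx3y was -0.026. Those genes end by position 1286629 of chromosome Y, whereas Mid1-ps1 starts at 90753057. They therefore say nothing about more copies of the region of Mid1-ps1 alone, which was not tested. Why the reads of at least 1 locus were so much more abundant stays open, and no biological explanation was tested.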
